A study of Mus musculus with 6 samples.

How the data were processed

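Polyadenylated RNA from isolated mouse pancreatic islets was measured in 6 libraries, 3 from islets kept at low (non-stimulating) glucose and 3 from islets kept at high (stimulating) glucose for 24 h. Islets are the clusters of endocrine cells that hold the insulin-secreting beta cells, and wild-type islets were used throughout. Per the labels' protocols, libraries were made from 500 ng of total RNA with poly-A selection and 9 PCR cycles. The glucose concentrations, the strain, and the number of animals behind each library were not given in the sources used here.

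The deposited values were counts of reads per gene, 1 column per library, with no normalization. Per the submitters' processing notes, STAR 2.7.3a and HTSeq 0.6.1p1 were used with the GRCm38 build. The annotation release, the strand setting, read filters and any use of molecular barcodes were not given in the sources used here. Without a stated strand setting, reads of overlapping and antisense genes could not be told apart. Genes with near-identical copies, such as the trypsin and amylase families and the H2 genes, have uncertain counts. Library totals ranged from 10596020 to 15846235 counts. Without molecular barcodes in the counting, intervals from counts cover counting error only.

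Columns were assigned to samples by their names, and groups and replicate numbers came from the labels. The table held 46983 genes, 23293 of them with at least 1 count. Gene names and coordinates were taken from GENCODE M21 on GRCm38. No name was found for 495 genes, which held 0.0141% of all counts. No row of totals or unassigned reads was present in the table. No pair of libraries differed by less than sampling noise, with a chi-square per degree of freedom of at least 16.2 within groups.

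High and low glucose were compared with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3. TMM scaling was used, filterByExpr with its defaults (minimum count 10, minimum total 15) kept 13996 genes, and Benjamini-Hochberg adjusted p under 0.05 was the threshold. Each standard error is the log2 fold change divided by the square root of F. CPM, counts scaled to a library of 1e+06, used TMM-scaled library sizes. Nothing in the labels says that the 3 libraries of a group came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical.

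A set of 41 gene lists and the rule for named genes were fixed before the data were examined. Lists with at least 5 measured members (40 of the 41) were tested with camera (limma 3.58.1) on log CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were run beside it. A further 6 marker lists (intestinal epithelium, hepatocyte, gastric epithelium, B-lymphocyte and plasma cell, adipocyte, acinar transcription factors) were added after the largest changes had been seen, and were adjusted among themselves. Some older symbols were matched by synonym.

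The named genes were, first, a fixed set (Ins1, Ins2, Gcg, Sst, Ppy, Txnip, Slc2a2, Pdx1, Mafa, Nox4, Cyba, G6pc2 and Pklr; the other members of the set are not reported here). Second came the 8 largest increases and 8 largest decreases past the threshold with a proper symbol, a mean of at least 10 CPM and no overlap of the libraries. Last, up to 3 changed members with the smallest p could be taken from each list. For genes with 1 to 3 counts in a group, the ratio of scaled counts is given with an exact 95% interval.

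Replicate numbers were shared between the groups, so pairing was checked on the deviations from the group means. The correlations of same-numbered libraries were 0.40, 0.26 and 0.25, and those of other pairs lay between -0.31 and 0.07. Deviations within a group sum to 0, so these correlations depend on one another and are weak evidence of pairing. No label states a pairing. The main fit was therefore left unblocked. A fit with the replicate number as a block, which gave 4670 changed genes, was run beside it.

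The alternatives were other scalings (DESeq2 size factors, library totals, the 20 most abundant genes left out), 2 other filters, DESeq2 1.42.0, limma-voom, a robust fit, a test against a fold of 1.2, the replicate block, and each library left out in turn. Scaling to the hormone and granule genes and leaving out exocrine and gut markers were added after the data had been examined.

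The fit was tested on simulated counts for the 13996 genes of this comparison. At a true 4-fold change 71 of 100 genes were recovered, and at 2-fold 12 of 100 were. Of 93 genes called, 10 were unchanged ones. Spearman correlations across genes of the log2 fold change with GC content and with exonic length were 0.018 and 0.0056, where genes are not independent replicates. Figures were drawn with matplotlib 3.10.9.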

Results

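RNA-seq counts were compared between mouse islets held for 24 h at high glucose and at low glucose, with 3 libraries in each group. The series addresses redox signaling and metabolic adaptation of beta cells to glucose. Totals were 12730985, 10596020 and 11694674 counts in low glucose replicates 1 to 3 and 15846235, 14643116 and 14150726 in high glucose replicates 1 to 3. The first principal component held 73.2% of the variance and separated the groups. The second held 13.6% and set high glucose replicate 1 apart.

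At high glucose 8 of 20 beta-cell identity genes fell (6 rose and 4 fell with library totals), 24 of 34 interferon-stimulated genes rose, and 25 of 28 acinar-cell markers fell. As lists, none of the 40 tested passed camera with an estimated correlation. The beta-cell transcription factor Mafa fell from 92.3 ± 3.00 to 6.89 ± 2.16 CPM (SD, n = 3 per group), and the glucose transporter gene Slc2a2 from 199 ± 75.6 to 4.35 ± 0.876 CPM. The heme oxygenase gene Hmox1 rose from 7.24 ± 1.81 to 153 ± 59.0 CPM, and Spp1, which encodes osteopontin, from 115 ± 30.9 to 2036 ± 565 CPM. The insulin genes Ins1 and Ins2 did not pass the test.

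In edgeR's quasi-likelihood test, 3848 of 13996 genes changed, 1861 higher and 1987 lower at high glucose. Of these, 2586 changed at least 2-fold, 1057 upward and 1529 downward. Groups did not overlap for 45.9% of tested genes, against 10% by chance if the libraries were exchangeable, a value that ignores any pairing. The count fell to 1743 without low glucose replicate 2 and to 1999 without high glucose replicate 3. Below, counts with 1 library left out name it as low 1 to 3 or high 1 to 3. With library totals as the scaling, the median log2 fold change of all genes moved from 0.01 to 1.16, and 8965 genes changed, 8337 higher and 628 lower. Directions below are relative to TMM scaling, and values with library totals are to be read against that shift. With sizes set by the hormone and granule genes, 1917 genes changed, 715 higher and 1202 lower.

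The makeup of the libraries differed between the groups. The 28 acinar markers, which encode digestive enzymes of the exocrine pancreas and their regulators, took 49.4%, 64.9% and 63.0% of the counts in low glucose replicates 1 to 3. At high glucose they took 12.8%, 25.3% and 24.7%. The 20 hormone and granule genes took 4.33%, 2.05% and 2.26% in the low and 10.1%, 3.70% and 4.36% in the high glucose libraries. The 10 most abundant genes took 50.5% ± 7.42 of the counts at low and 21.6% ± 4.79 at high glucose (SD, n = 3 each). Every gene group below was measured in libraries with these shares.

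**Figure D1:**
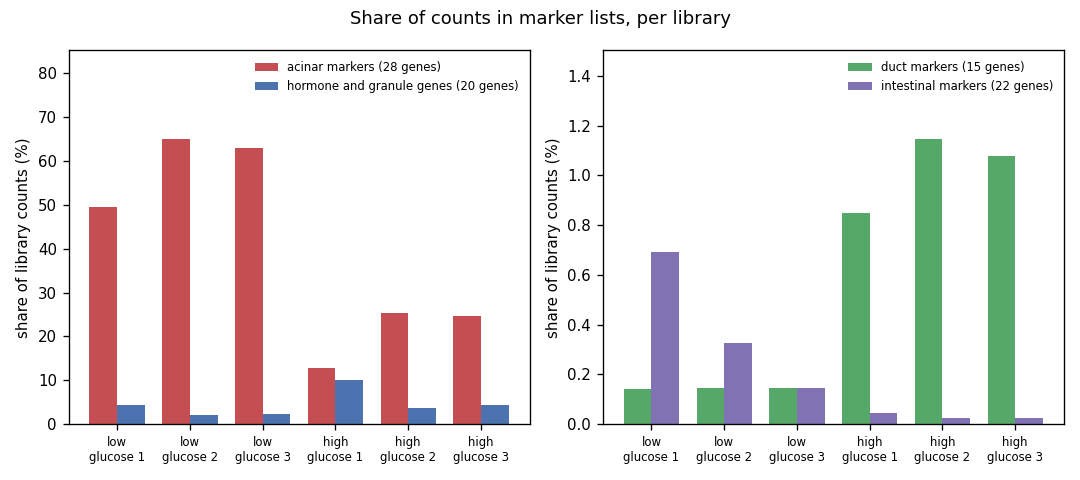
Share of library counts (%, linear axis from 0) in acinar markers and in hormone and granule genes (left) and in duct and intestinal markers (right), 1 bar per list and library. Acinar markers took 49.4% to 64.9% of the counts in the low glucose libraries and 12.8% to 25.3% in the high glucose libraries.

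Hormone transcripts did not pass the test. The log2 fold change (high minus low, ± SE) was -0.43 ± 0.44 for Ins1, -0.41 ± 0.51 for Ins2, -0.64 ± 0.38 for the glucagon gene Gcg, -0.21 ± 0.29 for the pancreatic polypeptide gene Ppy and -0.00 ± 0.31 for the somatostatin gene Sst. With library totals these were 0.76, 0.78, 0.50, 0.96 and 1.15, all in the other direction and below the median shift of 1.16, and of the 5 only Sst passed there. With the replicate block Gcg passed the edgeR test (log2 -0.67). Ins2 had 18359 ± 2294 CPM at low and 13772 ± 6656 CPM at high glucose (SD, n = 3 each). Among all 20 hormone and granule genes, 5 rose and 4 fell (6 and 4 adjusted over the list alone, 11 and 1 with library totals), and only 3 rose without low 2 and only 1 fell without high 3. Vgf, a granule protein precursor gene, rose by 3.61 ± 0.38 and the granule membrane gene Ptprn by 2.17 ± 0.31, whereas the granule zinc transporter gene Slc30a8 fell by 3.51 ± 0.28. The list's camera adjusted p was 0.711, and its median and mean differed in sign (-0.04 and 0.13).

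Of 20 beta-cell transcription factor and identity genes, 8 fell and none rose (11 fell adjusted over the list alone, 1 rose and 11 fell with the replicate block; 6 rose and 4 fell with library totals). Mafa, on chromosome 15 (75745490 to 75748228, GRCm38), fell by 3.74 ± 0.24 with an edgeR adjusted p of 4.01e-04. Slc2a2, on chromosome 3 (28697903 to 28731359), fell by 5.51 ± 0.35, and Trpm5, a cation channel gene, fell by 2.62 ± 0.22. Pdx1, on chromosome 5 (147269959 to 147275848), fell by 1.28 ± 0.27 with an edgeR adjusted p of 0.0131. Pdx1 did not pass without low glucose replicate 1 (-1.13) or replicate 2 (-1.31), nor with library totals (-0.12). The islet glucose-6-phosphatase gene G6pc2 (0.00 ± 0.41) did not pass. The list's median was -0.80 with a camera adjusted p of 0.00166, and 0.35 with library totals. This call was lost with adjusted p = 0.647 with an estimated correlation. With 1 library left out, 6 (without low 1 or low 2) to 13 (without high 1) members fell.

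Among 20 exocytosis and excitability genes, 3 rose and 2 fell (3 and 3 adjusted over the list alone, 13 and 0 with library totals; 2 and 0 with hormone and granule gene scaling). With 1 library left out, 0 (without low 2, low 3, high 2 or high 3) to 6 (without high 1) fell. Syt4, a synaptotagmin gene, rose by 1.96 ± 0.34. The list's camera adjusted p was 0.711. Of 15 measured genes that are normally kept low in beta cells, 4 rose and 2 fell (6 and 2 adjusted over the list alone, 12 and 0 with library totals), with a camera adjusted p of 0.146. From 1 (without low 2) to 7 (without high 1) of them rose with 1 library left out. The hexokinase gene Hk1 rose by 1.53 ± 0.18.

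**Figure D2:**
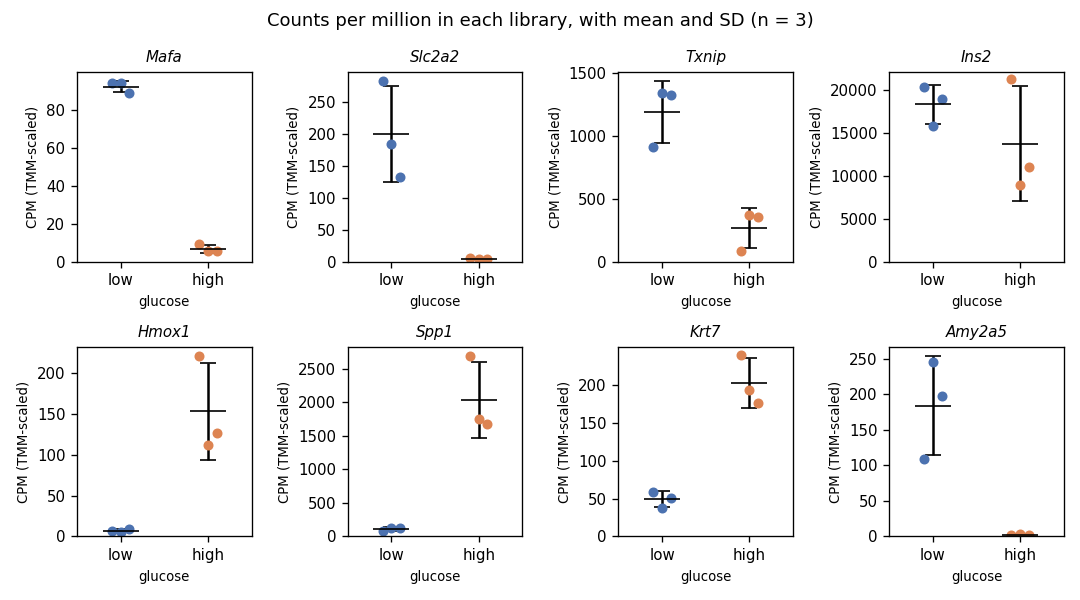
CPM values (TMM-scaled, linear axes from 0) of 8 genes in each library, with points for libraries, a horizontal line for the mean and bars for the SD (n = 3 per group). Mafa lay at 92.3 CPM at low and 6.89 CPM at high glucose on average, and Ins2 overlapped between the groups.

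Of 16 targets of ChREBP, a transcription factor activated by glucose metabolites, 8 fell and 2 rose (8 and 2 adjusted over the list alone, 5 and 5 with library totals). Txnip, which encodes an inhibitor of thioredoxin, lies on chromosome 3 (96557957 to 96561883). It fell by 2.15 ± 0.54, from 1192 ± 245 to 269 ± 159 CPM (SD, n = 3 each), with an edgeR adjusted p of 0.0237. Its call was lost without low glucose replicate 2 (-2.05) or 3 (-2.05), without high glucose replicate 3 (-2.38), with library totals (-1.02) and with hormone and granule gene scaling (-1.89). Pklr, the liver-type pyruvate kinase gene, fell by 2.48 ± 0.39, the fructokinase gene Khk fell by 3.36 ± 0.37, and Mlxipl, which encodes ChREBP, fell by 2.95 ± 0.39. The list had a median of -1.22 and a camera adjusted p of 0.0722, and it passed without low glucose replicate 3 (median -1.45), with library totals (-0.16) and with hormone and granule gene scaling (-1.05). Khk and Slc2a2 are also expressed by intestinal epithelium, whose markers fell as given below. In low glucose replicates 1 to 3 the median intestinal marker had 300, 180 and 69.8 CPM. Mlxipl (182, 108 and 59.3), Pklr (52.4, 46.5 and 18.9), Khk (49.5, 36.6 and 18.7) and Slc2a2 (282, 184 and 133) ran in the same order. Txnip (908.7, 1338.5 and 1328.3) did not. Islet genes such as Gcg (5752, 4167 and 4029), Sst (731, 599 and 518) and Pdx1 (79.6, 63.0 and 60.1) ran in that order too. Ins1 (8595, 6856 and 8279) did not. The order of the low glucose libraries is therefore no sign of an intestinal source. An intestinal part in the falls of these ChREBP targets was not tested.

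Of 19 glycolysis enzyme genes 9 rose and 2 fell (11 and 3 adjusted over the list alone, 15 and 2 with library totals), and 1 (without low 2) to 4 (without high 1) fell with 1 library left out. The phosphoglycerate kinase gene Pgk1 rose by 1.52 ± 0.17 and the aldolase A gene Aldoa by 1.53 ± 0.20, while Pklr fell. The list's median was 0.91 with a camera adjusted p of 0.0105, and adjusted p = 0.612 with an estimated correlation. Its median was 0.87 without high glucose replicate 1, where it was not called, and 2.04 with library totals, where it was not called either. Of 15 genes of the pentose phosphate pathway and NADPH supply, 5 rose and 2 fell (6 and 3 adjusted over the list alone, 11 and 0 with library totals), with a camera adjusted p of 0.289. Without low 2 or high 3 only 3 rose, and with hormone and granule gene scaling 2 rose and none fell. Pgd, which encodes an NADPH-producing dehydrogenase, rose by 1.46 ± 0.19.

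Of 46 nuclear respiratory chain and ATP synthase genes, 29 fell and none rose (34 adjusted over the list alone, 15 rose with library totals; 0 passed with hormone and granule gene scaling, median -0.52), with a median of -0.58 that became 0.61 with library totals. By camera, the adjusted p was 4.02e-09, and adjusted p = 0.606 with an estimated correlation. The ATP synthase gene Atp5o fell by 1.24 ± 0.16 (-0.04 with library totals, where it did not pass). Of 26 genes of the TCA cycle and pyruvate entry, 14 fell and 1 rose (19 and 2 adjusted over the list alone, 10 rose with library totals; 1 fell with hormone and granule gene scaling, median -0.49). Their median was -0.59, or 0.60 with library totals, with a camera adjusted p of 2.63e-04 and adjusted p = 0.606 with an estimated correlation. The pyruvate carboxylase gene Pcx fell by 1.44 ± 0.18, but with library totals (-0.23) it did not pass. Neither list was called with library totals. With 1 library left out, 5 (without low 2) to 33 (without high 1) respiratory chain genes and 3 (without high 2 or high 3) to 12 (without low 1 or high 1) TCA genes fell. Transcripts of the mitochondrial genome were hardly counted, at 79 to 197 protein-coding counts per library. Of the 13 such genes 4 were measured, and 2 fell (3 adjusted over the list alone, 1 with the replicate block, 0 with library totals, 0 without low 2, low 3, high 2 or high 3).

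Cholesterol synthesis genes rose in 7 of 25 cases and fell in 1 (7 and 1 adjusted over the list alone, 21 and 0 with library totals; 4 and 0 with hormone and granule gene scaling), and 3 (without low 2) to 10 (without high 1) rose with 1 library left out. Fdft1, the squalene synthase gene, rose by 1.21 ± 0.14 and the lanosterol demethylase gene Cyp51 by 1.08 ± 0.20, although Cyp51 did not pass with hormone and granule gene scaling (1.22). Camera gave an adjusted p of 0.0165, and adjusted p = 0.606 with an estimated correlation. That list was not called with library totals (median 1.48). Fatty acid synthesis genes rose in 4 and fell in 4 of 20 cases (4 and 4 adjusted over the list alone, 4 and 7 with the replicate block; 13 and 1 with library totals; 1 and 2 with hormone and granule gene scaling), with a camera adjusted p of 0.557. Without low 2 none of these rose and 1 fell, and without high 3 none rose. In fatty acid oxidation and PPAR targets, 11 of 29 fell and 5 rose (12 and 5 adjusted over the list alone, 3 fell and 11 rose with library totals; 5 and 4 with hormone and granule gene scaling). Leaving out low 2 gave 5 lower and 2 higher, and leaving out high 1 gave 13 lower and 9 higher. Hadh, a beta-oxidation enzyme gene, fell by 2.46 ± 0.19, while Plin2, a lipid droplet coat gene, rose by 3.45 ± 0.35. In the camera test, adjusted p was 0.112 for this list, which passed without low glucose replicate 3 (median -0.38).

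NRF2 targets, which include enzymes against oxidative stress, rose in 14 of 22 cases and fell in 2 (15 and 2 adjusted over the list alone, 17 and 0 with library totals; 9 and 2 with hormone and granule gene scaling). The cystine transporter gene Slc7a11 rose by 4.42 ± 0.28, Hmox1 by 4.40 ± 0.34 and the autophagy receptor gene Sqstm1 by 2.33 ± 0.25. The median was 1.02 with a camera adjusted p of 2.28e-05, and adjusted p = 0.606 with an estimated correlation. The call was lost when members shared with other lists were left out (median 0.66). Among 33 measured antioxidant and thiol redox genes, 5 rose and 6 fell (8 and 7 adjusted over the list alone, 21 and 2 with library totals; 10 and 8 without high 1; 3 and 4 with hormone and granule gene scaling), with a camera adjusted p of 0.711. Nnt, the mitochondrial transhydrogenase gene, fell by 1.66 ± 0.18, but with library totals (-0.44) it did not pass.

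Of 11 measured NADPH oxidase genes, which encode superoxide-producing enzymes and their subunits, 0 passed by edgeR, 0 adjusted over the list alone, 0 had an unadjusted p under 0.05, and DESeq2 and limma-voom gave 0 each. Library totals gave 4 higher, leaving out high 1 gave 2 higher and 2 lower, and leaving out low 1 gave 1 lower. The camera adjusted p of the list was 0.295. The subunit gene Cyba had 10.8 ± 1.84 CPM at low and 9.26 ± 0.983 CPM at high glucose (SD, n = 3 each), a log2 fold change of -0.21 ± 0.20 that became 0.98, past the threshold but below the median shift, with library totals. Nox4 was below the filter, with 9 counts over the low and 7 over the high glucose libraries, a TMM-scaled low to high ratio of 3.60 (exact 95% interval 1.19 to 11.4, counting error only). That interval holds for TMM scaling only. The ratio was not computed with library totals, where all genes shifted toward high glucose (median log2 fold change 1.16).

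Of 26 measured NF-kappaB and cytokine genes, 13 rose and none fell (15 adjusted over the list alone, 22 with library totals). The neutrophil chemokine gene Cxcl1 rose by 5.52 ± 0.42 and Lcn2, which encodes lipocalin 2, by 6.49 ± 0.32. Of 34 interferon-stimulated genes 24 rose and none fell (26 rose and 1 fell adjusted over the list alone, 28 and 1 with the replicate block; 31 and 0 with library totals), and 13 rose without low 2. The transcription factor gene Irf9 rose by 1.73 ± 0.20 and the RNA sensor gene Ddx58 by 1.41 ± 0.17. In the camera test, adjusted p was 3.72e-07 for the cytokine list and 4.32e-09 for the interferon list, and each had adjusted p = 0.606 with an estimated correlation.

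Immediate early genes rose in 17 of 29 cases and none fell (19 rose and 2 fell both adjusted over the list alone and with the replicate block; 21 rose with library totals; 2 fell without high 1). Ier3 rose by 4.96 ± 0.39, and the AP-1 subunit gene Fosl2 by 1.46 ± 0.14. Targets of p53 rose in 15 of 25 cases and fell in 3 (16 and 4 adjusted over the list alone, 16 and 5 with the replicate block; 20 and 1 with library totals). The cell-cycle inhibitor gene Cdkn1a rose by 2.39 ± 0.38 and Phlda3 by 4.15 ± 0.57. In the camera test, adjusted p was 7.49e-06 for immediate early genes and 0.00451 for p53 targets, with adjusted p = 0.606 and adjusted p = 0.647 with an estimated correlation. The p53 list was not called with library totals (median 2.50). Without low 2 only 9 immediate early genes and 7 p53 targets rose, against 18 of each without high 1.

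Targets of ATF4, the transcription factor of the integrated stress response, rose in 13 of 32 cases and fell in 3 (15 and 3 adjusted over the list alone, 26 and 1 with library totals; 8 and 3 with hormone and granule gene scaling), and 8 rose without low 1 or without low 2. Gdf15, a stress-induced secreted factor gene, rose by 6.24 ± 0.59 and Cebpb by 2.15 ± 0.21. Tested with camera, the list had an adjusted p of 0.00347, and adjusted p = 0.647 with an estimated correlation. It was not called without low glucose replicate 1 (median 0.61). Of 20 cytosolic aminoacyl-tRNA synthetase genes 2 rose and none fell (1 adjusted over the list alone, 6 rose and 1 fell with the replicate block; 19 rose with library totals; 1 with hormone and granule gene scaling), and 0 (without low 2) to 6 (without low 3 or high 1) rose with 1 library left out. Rars rose by 1.49 ± 0.30, but it did not pass without low glucose replicate 2 (1.45). The camera adjusted p was 0.0364, and adjusted p = 0.714 with an estimated correlation. The call was lost without low glucose replicate 1 (median 0.16), without high glucose replicate 2 (0.21) and with hormone and granule gene scaling (0.46).

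Endoplasmic reticulum folding genes fell in 9 of 32 cases and rose in 3 (10 and 3 adjusted over the list alone, 4 fell and 17 rose with library totals; 5 and 1 with hormone and granule gene scaling; 1 rose without low 1 or low 2), with a median of -0.35, or 0.89 with library totals. Sel1l, an adaptor gene of protein degradation, fell by 2.97 ± 0.28 and the oxidoreductase gene Ero1lb fell by 2.62 ± 0.27. By camera, the adjusted p was 0.0346, and adjusted p = 0.714 with an estimated correlation. The call was also lost with the replicate block (median -0.33), library totals, hormone and granule gene scaling (-0.32), and without low glucose replicate 3 (-0.15), high glucose replicate 2 (-0.29) or high glucose replicate 3 (-0.31). The share of acinar markers, whose cells are rich in folding transcripts, was 2.83 times higher at low glucose. The folding list itself took 0.951% of the counts at low and 1.44% at high glucose. An acinar part in its fall was not tested.

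Ribosome biogenesis genes rose in 19 of 30 cases and none fell (25 adjusted over the list alone, 30 with library totals), among them Nop58 by 1.13 ± 0.18. With hormone and granule gene scaling 1 of the 30 passed (median 0.99) and Nop58 did not (1.28), and 6 (without low 2) to 24 (without high 1) rose with 1 library left out. Lysosome and autophagy genes under TFEB rose in 13 of 34 cases and fell in 1 (15 and 1 adjusted over the list alone, 31 and 0 with library totals; 6 and 0 with hormone and granule gene scaling; 5 rose without low 2; 3 fell without high 1), and Gla, the alpha-galactosidase gene, rose by 2.39 ± 0.30. In the camera test, adjusted p was 6.14e-08 for ribosome biogenesis and 0.00146 for lysosome genes, with adjusted p = 0.612 and adjusted p = 0.606 with an estimated correlation. Hypoxia targets rose in 9 of 25 cases and fell in 1 (11 and 1 adjusted over the list alone, 12 and 2 with the replicate block; 21 and 0 with library totals), and the glucose transporter gene Slc2a1 rose by 2.95 ± 0.24. Cytosolic heat shock genes rose in 4 of 16 cases and none fell (4 adjusted over the list alone, 15 with library totals; 2 with hormone and granule gene scaling), and 1 (without low 2 or high 3) to 7 (without high 1) rose with 1 library left out. The co-chaperone gene Bag3 rose by 0.92 ± 0.17, but with hormone and granule gene scaling (0.97) it did not pass. In the camera test, adjusted p was 0.00425 for hypoxia and 0.00258 for heat shock genes, with adjusted p = 0.612 and adjusted p = 0.606 with an estimated correlation. The hypoxia call was lost when members shared with other lists were left out (median 0.29).

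Genes of G2 and mitosis fell in 8 of 28 cases and rose in 1 (8 and 1 adjusted over the list alone, 13 fell and none rose with the replicate block; 4 rose with library totals). With 1 library left out, 1 (without low 1, low 3 or high 3) to 13 (without high 1) fell, and 12 fell with hormone and granule gene scaling. The spindle gene Hmmr fell by 2.35 ± 0.46 from low counts (68 over the low and 37 over the high glucose libraries), and it did not pass with library totals (-1.20). The median was -1.56 with a camera adjusted p of 0.00359, and adjusted p = 0.612 with an estimated correlation. S phase genes rose in 8 and fell in 3 of 29 cases (9 and 3 adjusted over the list alone, 17 and 0 with library totals; 3 and 1 with hormone and granule gene scaling; 3 rose without low 2; 0 fell without low 1, low 3, high 2 or high 3), with a camera adjusted p of 0.216. The helicase gene Mcm6 rose by 1.61 ± 0.23. Of 19 regulators of beta-cell growth 4 rose and 5 fell (5 and 5 adjusted over the list alone, 10 and 0 with library totals; 3 and 3 with hormone and granule gene scaling; 0 fell without high 3), with a camera adjusted p of 0.8, and the growth factor receptor gene Igf1r rose by 2.56 ± 0.22. FOXO targets rose in 3 and fell in 6 of 20 cases (4 and 8 adjusted over the list alone, 11 and 2 with library totals; 1 and 3 with hormone and granule gene scaling; 1 rose without low 1, low 2, low 3 or high 3), with a camera adjusted p of 0.172, and Klf15 fell by 3.33 ± 0.35. Clock genes rose in 4 and fell in 4 of 18 cases (4 and 5 adjusted over the list alone, 6 and 0 with library totals; 3 and 0 with hormone and granule gene scaling; 0 fell without low 2, high 2 or high 3; 2 rose without low 2), with a camera adjusted p of 0.441. Bhlhe40, a repressor gene of the clock that is also a hypoxia target, rose by 2.07 ± 0.22.

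Of 28 acinar markers 25 fell and none rose (27 adjusted over the list alone, 22 with library totals; 14 without low 2 or high 3), with a median of -2.88, or -1.67 with library totals. The amylase gene Amy2a5 fell by 6.34 ± 0.46 and the chymotrypsin C gene Ctrc fell by 3.79 ± 0.43, and counts in these families can include reads of close paralogs. Camera gave an adjusted p of 5.66e-13, and adjusted p = 0.606 with an estimated correlation. Duct markers split, with 6 of 15 higher and 4 lower (6 and 5 adjusted over the list alone, 9 and 2 with library totals; 6 and 2 with hormone and granule gene scaling; 1 lower without low 2) and a camera adjusted p of 0.528. Spp1 rose by 4.15 ± 0.37 and the keratin gene Krt7 by 2.05 ± 0.23. Duct markers took 0.145% ± 0.00164 of the counts at low and 1.02% ± 0.157 at high glucose (SD, n = 3 each).

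Among other islet endocrine markers, 3 of 14 alpha-cell markers fell and 1 rose (6 and 1 adjusted over the list alone, 7 and 1 with the replicate block and without high 1; 1 and 1 with library totals), with a median of -0.76, or 0.34 with library totals. The amino acid transporter gene Slc38a5 fell by 3.48 ± 0.37 and the transthyretin gene Ttr fell by 1.65 ± 0.27, whereas the vitamin D-binding protein gene Gc rose by 1.53 ± 0.29. Ttr did not pass with library totals (-0.54). Tested with camera, the list had an adjusted p of 0.00451, and adjusted p = 0.612 with an estimated correlation. Of 7 measured delta-cell markers 2 fell (2 adjusted over the list alone, 1 fell and 3 rose with library totals; 3 fell and 1 rose without high 1; 1 fell with any 1 of the other libraries left out), with a camera adjusted p of 0.225, and Bche fell by 5.49 ± 0.52. With library totals the list passed camera in the downward direction, relative to the other genes. Its median there was 1.15, against 1.16 for all genes. The list of PP and epsilon cells had 0 of 6 past the edgeR threshold (0 adjusted over the list alone, 1 at an unadjusted p under 0.05, 0 by DESeq2, 0 by limma-voom, 2 lower with the replicate block, 1 higher with library totals, 3 lower without high 1), with a camera adjusted p of 0.227.

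Fibroblast, stellate and pericyte markers fell in 5 of 18 cases (6 adjusted over the list alone, 9 with the replicate block; 2 with library totals; 8 with hormone and granule gene scaling; 16 without high 1, median -2.16; 3 without low 2 or high 3), with a median of -1.21, or 0.05 with library totals. The smooth muscle actin gene Acta2 fell by 3.62 ± 0.43 and the pericyte gene Rgs5 fell by 1.75 ± 0.19, and Rgs5 did not pass with library totals (-0.62). The camera adjusted p was 2.27e-04, and adjusted p = 0.612 with an estimated correlation. Macrophage and leukocyte markers had 1 of 19 lower and 1 higher (1 and 1 adjusted over the list alone, 11 and 1 with the replicate block; 15 and 1 without high 1, median -2.34; 0 and 1 with library totals; 7 and 1 with hormone and granule gene scaling), with a median of -1.06, or 0.17 with library totals. The complement gene C1qa fell by 2.11 ± 0.44, and with library totals (-0.86) it did not pass. By camera, the adjusted p was 0.00364, and adjusted p = 0.647 with an estimated correlation. Endothelial markers fell in 2 of 15 cases (0 adjusted over the list alone, 5 lower and 1 higher with the replicate block; 3 higher with library totals; 8 lower without high 1; 0 lower with any 1 of the other libraries left out), with a camera adjusted p of 0.136, and the list passed without high glucose replicate 1 (median -0.69). Schwann-cell and neuron markers fell in 2 of 10 cases (2 adjusted over the list alone, 3 rose with library totals; 0 fell without high 3), with a camera adjusted p of 0.295.

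After the largest changes had been seen, 6 further marker lists were tested. All 19 measured markers of intestinal epithelium fell, 19 adjusted over the list alone and 17 with library totals, with a median of -5.66 and a camera adjusted p of 1.43e-12 (adjusted p = 0.274 with an estimated correlation). Their share of the counts was 0.387% ± 0.278 at low and 0.0322% ± 0.0126 at high glucose (SD, n = 3 each). Of 7 acinar transcription factors 2 fell (3 adjusted over the list alone, 6 with the replicate block; 2 with library totals; 4 without high 1 or high 2), with a median of -1.36 and a camera adjusted p of 0.00724 (adjusted p = 0.274 with an estimated correlation). B-lymphocyte and plasma-cell markers fell in 2 of 8 cases (2 adjusted over the list alone, 0 with library totals; 5 without high 1 and 0 without low 1, low 2, low 3, high 2 or high 3), with a camera adjusted p of 0.03 (adjusted p = 0.438 with an estimated correlation) and a median of -1.08, or 0.13 with library totals. Of 5 measured hepatocyte markers 3 fell and 1 rose (3 and 1 adjusted over the list alone, 2 and 1 with library totals), with a camera adjusted p of 0.0811. Too few members were measured to test gastric epithelium (1 of 2 rose and 1 fell, the same adjusted over the list alone, 1 rose with library totals; 0 fell without low 1, low 2 or low 3) and adipocytes (1 of 3 fell; 2 adjusted over the list alone, 2 with the replicate block; 2 without low 3; 1 fell and 1 rose with library totals).

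Among genes with a mean of at least 10 CPM and no overlap of the libraries, the 8 largest increases were those of Sprr1a (7.95 ± 0.59), Lcn2, Fosl1 (6.25 ± 0.46), Gdf15, Fgb (6.10 ± 0.47), Gsdma (5.97 ± 0.37), Cldn4 (5.47 ± 0.59) and Rgs4 (5.40 ± 0.22). These encode an epithelial envelope protein, lipocalin 2, an AP-1 subunit, a stress-induced factor, the fibrinogen beta chain, a gasdermin, a tight junction protein and a regulator of G-protein signaling. Rgs4 rose from 8.64 ± 0.822 to 366 ± 51.0 CPM (SD, n = 3 each) with an edgeR adjusted p of 9.84e-05.

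Among the 8 largest decreases by the same rule, Sis, the sucrase-isomaltase gene, had 4059 counts over the low and 4 over the high glucose libraries and fell by 11.07 ± 0.98. The lactase gene Lct fell by 10.37 ± 0.90 and the cytochrome gene Cyp3a11 fell by 10.36 ± 1.35, with edgeR adjusted p of 7.30e-04 and 0.00237. Scaled counts of the sulfate transporter gene Slc13a1 were 1818 times higher at low glucose (exact 95% interval 502 to 15030), from 1298 and 2 counts. The low to high ratio was 1796 (321 to 71040) for H2-T3, 1476 (408 to 12210) for Cyp3a25, 1202 (332 to 9940) for the carboxylesterase gene Ces1f and 895 (247 to 7407) for Ces2b. High glucose libraries held 1 count of H2-T3 and 2 of each of the other 3 genes, and these 4 genes have close paralogs with which they may share reads. All these intervals cover counting error only. The low glucose libraries differed widely, with 10 to 382 counts of Ces2b.

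**Figure D3:**
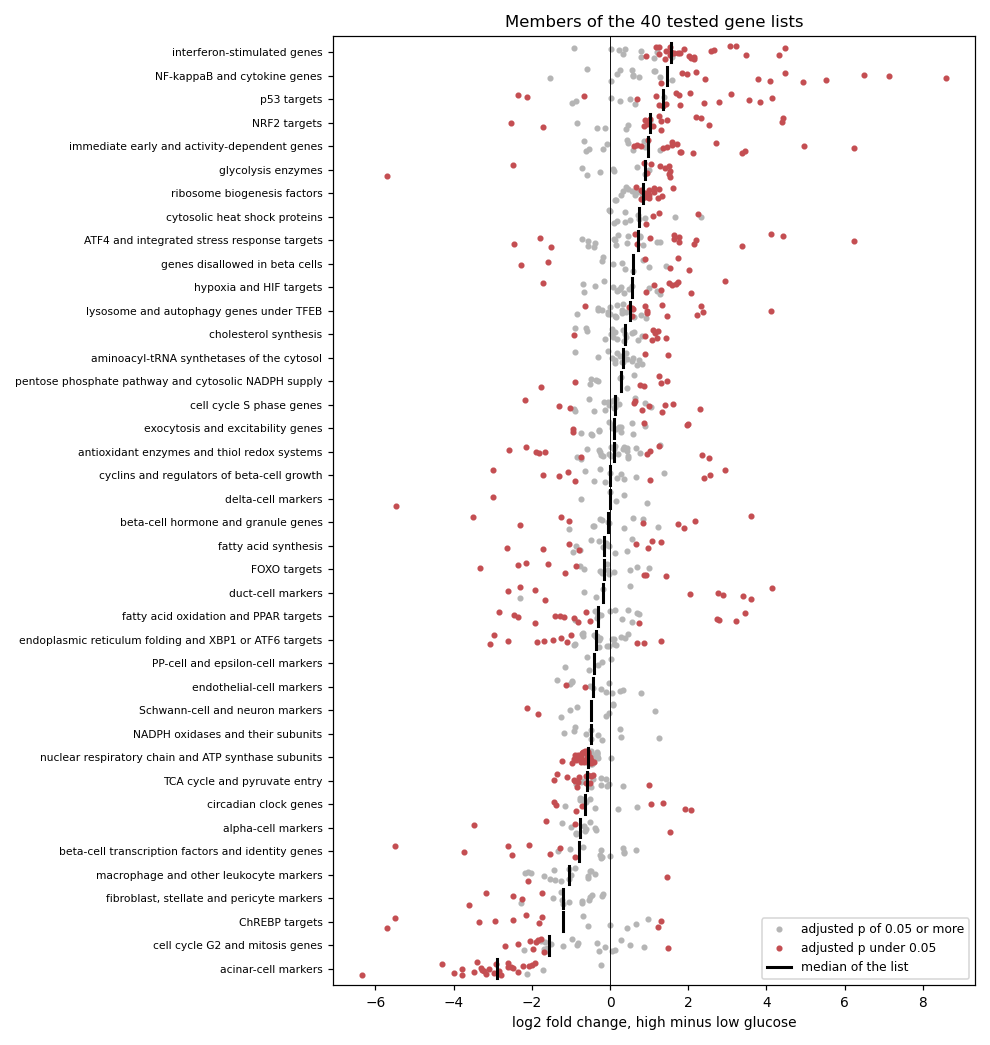
Log2 fold changes (high minus low glucose, TMM scaling) of the measured members of 40 gene lists, with red points for genes at an edgeR adjusted p under 0.05, grey points for the others and a black bar for each list's median. Medians ran from -2.88 for acinar markers to 1.55 for interferon-stimulated genes; with library totals the median of all genes lay 1.16 higher and several medians below 0 changed sign.

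Of the 40 lists tested with camera, 22 passed an adjusted p of 0.05, 13 upward and 9 downward. None passed with an estimated correlation, where adjusted p lay between 0.606 and 0.923. By fry, which does not compare a list with other genes, 35 lists passed for change in either direction and 19 for change on balance in 1 direction.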

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

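Scaling to the hormone and granule genes and leaving out exocrine and gut markers were chosen after the data were examined. The number of changed genes in each direction depended on the scaling. With library totals, 2487 of the 3848 genes passed in the same direction and 7 in the opposite one. Library totals gave 8965 changed genes, 8337 higher and 628 lower, and 8123 changed at least 2-fold. They also gave log2 fold changes of 0.76 for Ins1, 0.78 for Ins2, 0.50 for Gcg, 1.15 for Sst, 0.96 for Ppy and 0.98 for Cyba, and list medians of 1.14 for hormone and granule genes and 1.06 for duct markers. The median of all genes moved to 1.16 there, and acinar transcripts took more counts at low glucose. Scaling to hormone and granule genes gave 1917 genes, 715 higher and 1202 lower, and G6pc2 lay at -0.031. The cause was not tested. The count stayed between 2993 and 4670 under the 10 other settings that kept all 6 libraries.

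G6pc2 was -0.0024 with DESeq2 size factors, -0.0089 with a mean CPM of at least 1, -0.0024 by DESeq2, -0.045 by limma-voom and -0.051 with the replicate block. Sst was 0.0075 without the 20 most abundant genes, 0.091 with no expression filter and 0.0023 with exocrine and gut markers left out. With members shared between lists left out, medians were -0.31 for the pentose phosphate list, 0.019 for antioxidant genes and -0.057 for growth regulators, from fewer genes. With the estimated correlation 0 of 40 lists passed, against 22 with the preset one; 0 were called by that tool although fry called 35.

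Leaving out 1 library at a time gave 1743 to 5685 changed genes, 708 to 2793 higher, 1035 to 2892 lower and 1557 to 3538 changed at least 2-fold, each lowest without low glucose replicate 2 and highest without high glucose replicate 1. Log2 fold changes ran from -0.34 to 0.17 for Sst, -0.45 to 0.021 for Ppy and -0.50 to 0.33 for G6pc2. List medians ran from -0.43 to 0.13 for hormone and granule genes, -0.27 to 0.28 for exocytosis genes and 0.017 to 0.12 for antioxidant genes. For antioxidant genes it was camera's direction that changed, without low glucose replicate 1. High glucose replicate 1 held the largest hormone and granule share, 10.1% of its counts.

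Of 80 named genes with a fold change, 73 passed, and 60 did so under every alternative run. Most of them were named because they passed in these data, so these counts do not measure how stable the calls are. Of all 3848 changed genes, 44.4% (without low glucose replicate 2) to 99.25% (robust fit) passed in the same direction under an alternative. With library totals 64.6% did. In simulated counts with few changed genes, 12 of 100 genes with a true 2-fold change were recovered, under a stricter adjusted threshold than 3848 changed genes give.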

Other observations

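Tests of acinar state, of scaling and of the beta-cell share were chosen only after the result was seen, as were the genes Ctrb1, Rnase1, Ucn3, Alb, Cdx1, Cdx2 and Vil1. The test of acinar state was also rewritten once before it was run: it first used only the ratio of Ctrb1 to Rnase1, and a bound on the spread over all acinar markers was then added. Within the acinar markers, enzymes moved unequally. The log2 ratio of Ctrb1, a chymotrypsinogen gene, to Rnase1, a ribonuclease gene, was 1.17 ± 0.10 at low and 3.70 ± 0.07 at high glucose (SD, n = 3 each), with no overlap of the libraries. Rnase1 fell by 4.29 ± 0.68 (edgeR adjusted p 0.00481), and Ctrb1 (-1.72 ± 0.73, edgeR adjusted p 0.116) did not pass. Reads shared with paralogs were not separated.

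Acinar transcripts took 59.1% of the counts at low and 20.9% at high glucose. The fall did not depend on TMM, since the median of the markers was -1.67 with library totals. That value restates these shares of the counts, so it is no separate test of scaling as a cause. Fewer acinar cells in an unchanged state would leave ratios between acinar transcripts unchanged. The log2 ratio of Ctrb1 to Rnase1 differed by 2.54, past the bound first written and far beyond the SDs within groups. For these 2 genes, picked after the result was seen, that argues against an unchanged state. For the markers as a set the question stayed undecided. The SD of their log2 fold changes (1.06) was 1.76 times their median SE (0.603), short of the 2 times added later. Each SE also holds library variation that the markers share (estimated correlation 0.726), so that bound cannot decide. A changed acinar state and glucose itself may also contribute and were not separated from a loss of acinar cells.

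Intestinal transcripts lay in the low glucose libraries, with 87790, 34560 and 16920 marker counts against 7382, 3522 and 3650. Intestinal epithelium in that material is a candidate source: 19 of 19 measured markers fell with a median log2 fold change of -5.66. That list was added after the largest changes had been seen, and its members could pass the filter through the low glucose libraries alone. Cdx1 and Cdx2 together had 162, 52 and 16 counts in the low glucose libraries against 2, 0 and 2. Liver tissue was argued against, since Alb, with 21, 21 and 18 counts, reached at most 0.0405 of the median intestinal marker. Pancreas also expresses some of these genes, among them Vil1 and Anpep, and no test separated carried-over tissue from induced expression or from an effect of glucose.

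Txnip and other ChREBP targets (8 of 16), which glucose metabolism is known to raise, were lower in the libraries named high glucose, as were 8 of 20 beta-cell identity genes. A lower share of beta cells alone would lower beta-cell transcripts by a like factor. Log2 fold changes of the 20 identity genes ran from -5.51 to 0.67. Ins1 (-0.43 ± 0.44) and Ins2 (-0.41 ± 0.51) did not pass. These values argue against a lower share as the only cause for the identity genes. A part in their falls, or in that of Txnip, stays open. Scaled to hormone and granule genes, Txnip and the 8 identity genes had a median of -2.19 (median SE 0.378), against -2.15 with TMM, and 7 of the 9 still passed. The 8 had been chosen because they fell in these libraries, and the scalings hardly differed (median of all genes 0.10 against 0.01 with TMM). A median below -1 therefore followed from the choice and by itself decides nothing. The test had been rewritten after its values were known. Earlier forms used Mafa, Pdx1, Slc2a2 and Ucn3 (median -2.97), and then all 20 identity genes (median -0.77, between the bounds of -0.5 and -1, so undecided). Exchanged glucose labels cannot be told apart from the labels as given. The 10 ChREBP targets not seen before the test of that had a median of -0.13 (SD 1.77), with 2 higher (Arrdc4, Klf10) and 4 lower (Mlxipl, Gpd1, Tkfc, Khk). With library totals their median was 0.96, where that of all genes was 1.16. Mlxipl and Khk followed the order of the intestinal markers in the low glucose libraries, but so did islet genes such as Gcg and Pdx1. An intestinal part in the falls of Mlxipl and Khk was not tested. Handling that followed the groups also stays open, since 30 of 55 immediate early and cytokine genes passed and no label separates handling from glucose. Time in culture was 24 h in both groups by the labels. Glucose itself stays among the open explanations, untested.

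The split of the 6 libraries by glucose gave 3848 changed genes, 2586 changed at least 2-fold and 22 lists, and no other split gave as many (1 of 10 in each case). The highest other splits gave 0, 0 and 19, and 10 splits are too few for a share under 0.05. By edgeR the other splits had at most 1203 genes at an unadjusted p under 0.05, against 5810. Of the 4 splits that part all 3 numbered pairs, the other 3 gave at most 17 lists, and the 6 that part 1 pair gave at most 19. Each other split keeps 2 libraries of a glucose group together, so part of the glucose difference stays in it.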
